A study of Arabidopsis thaliana with 7 samples.

How the data were processed

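The series holds immunoprecipitations of cyclobutane pyrimidine dimers, the main photolesion that UV-C makes between neighbouring pyrimidines, from seedlings of wild-type Arabidopsis thaliana Col-0. Plants were 3 weeks old, grown in 16 h light and 8 h dark, and the UV dose in the labels was 3000 J per square metre of UV-C. There were 4 libraries from UV-treated plants, 2 from plants labelled as not treated and 1 input library without antibody. The input had no peak list of its own here and entered no comparison. The labels number the replicates without saying whether they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

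Each immunoprecipitated library came with 1 list of peaks. Per the file headers and names, the authors called peaks per library against pooled input, and per the submitters' processing notes the tools were CASAVA 1.8.2, Bowtie and MACS2 on the TAIR10 genome. The role and settings of these tools and the peak threshold are not given in the sources used here. Each peak carries a deposited score given by the authors, and which MACS2 quantity it is stays unknown. Scores were used only to rank or filter peaks within their own list. Read numbers are unknown, so the length of a list may follow sequencing depth as well as the number of lesions, and no value here corrects for that.

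Most peaks of a list had 1 width, the narrowest in that list, which ranged from 122 to 147 bp between libraries. Between 62.3% and 85.7% of the peaks of a library were that narrow, so a median width mostly states this floor.

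Lists were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Peaks of all 6 libraries were merged into regions where they overlapped by at least 1 bp. A region can therefore be a chain of peaks, in which peaks of different libraries need not overlap each other. A UV-only recurrent region had a peak in at least 2 of the 4 UV libraries and in neither untreated library. Per-library values were compared by an exact permutation test over the 15 splits of the 6 libraries into 4 and 2, two-sided unless stated. The smallest p this design allows is 0.0667, so no group comparison could pass 0.05. Group values are means ± SD. Shares of 1 library carry exact Clopper-Pearson 95% intervals, which cover counting error only.

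Observed overlaps and shares were set against 1000 random placements of the same peaks, each on its own chromosome with its own width. Placement ran from the first to the last peak of any library on a chromosome. Nuclear assembly gaps and repeats were not left out, as that needs a genome sequence, so placed nuclear peaks can fall where no peak could be called. This lowers the nuclear overlaps expected and raises the expected share of gap-rich sequence, to an extent not measured. On the organelles, stretches of more than 10 kb without a peak in any library were left out. Placement p-values are permutation p-values. They were adjusted by Benjamini-Hochberg for pairs of libraries, shares of peaks, gene lists and groups of chloroplast genes, and p-values of region counts and of peaks on 1 gene are unadjusted. The smallest two-sided p these placements can give is 0.002, and the smallest one-sided p is 0.001. The code for merging, placement and splits was tested on simulated data: of 40 UV-only regions planted in each of 50 sets of random nuclear lists of the real lengths, 99.65% were recovered, and of 10 regions planted in all 6 libraries, 100% were.

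Genes were taken from a RefSeq table of the TAIR10.1 assembly. That its nuclear and chloroplast coordinates are those of TAIR10 was assumed, not tested against sequence, and gene assignments rest on it. Coordinates printed are those of the peaks on TAIR10, counted from 1. Mitochondrial peaks were not assigned to genes. A peak was in a gene when its midpoint lay in the gene body. The table gives no exons or strand, so the split into exon, intron, UTR and promoter was not analysed here. Shares in transposable element genes, dipyrimidine content, GC content, repeated sequence and lists by description words, though planned, needed a genome or annotation not used here. Pericentromeres were the runs of 100 kb windows around the window of lowest protein-coding gene density in which the 500 kb running mean stayed under 0.5 of the chromosome mean, with gene bodies in place of the planned exons.

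Tests, named-gene rule and gene lists were fixed before the data were examined. Regions were ranked by the number of UV libraries with a peak, then by the mean percentile of the score within its own list, then by position. Named were the 15 highest UV-only recurrent regions, the 8 highest regions found in all 6 libraries, up to 5 regions found in both untreated libraries and no UV library, and every member of the 4 identifier lists with a peak. The pseudogene share of peaks and the plots of wide peaks were added after the data were seen. Regions named outside this rule are said to be chosen after their values were seen. The identifier lists held 13 genes of nucleotide excision repair and damage recognition, 2 photolyases, 4 genes of UV-B and light response and 10 genes of RNA silencing. Lists by gene class held rRNA, tRNA, snoRNA with snRNA, miRNA genes and pseudogenes. The pseudogene class held 4843 genes. The annotation used has no class of transposable element genes, so these may be counted among pseudogenes. Alternatives left out each library, used a block of the shared replicate numbers, kept only peaks above the median score of their list, equalised list lengths at 228 peaks, asked for an overlap of 0.5 of the shorter peak, or kept nuclear chromosomes alone. Keeping the same fraction of each list by score was added after the data were seen.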

Results

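DNA carrying cyclobutane pyrimidine dimers was immunoprecipitated from Arabidopsis seedlings with or without UV-C treatment, to ask where in the genome these lesions lie after exposure. The 4 UV libraries gave 562, 228, 449 and 677 peaks in replicates 1 to 4, and the 2 untreated libraries gave 433 and 587. Read depth is unknown, so the number of peaks is the only measure of each library's size. The untreated libraries show what the same antibody and peak calling gave without the treatment.

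UV libraries held no more peaks on average than untreated ones. The mean was 479 ± 191 peaks (SD, n = 4) with UV and 510 ± 109 (SD, n = 2) without (exact permutation p = 0.867). On the 5 nuclear chromosomes the means were 364 ± 132 with UV and 458 ± 87.0 without (exact permutation p = 0.467, n = 4 and 2). Peaks covered 87596 ± 41492 bp per UV library (n = 4) and 70179 ± 14793 bp per untreated library (n = 2, exact permutation p = 0.667). The median width was 138 ± 10.5 bp with UV (n = 4) and 125.5 ± 4.95 bp without (n = 2, exact permutation p = 0.2). Without UV replicate 2, the shortest list, the UV mean was 52.7 peaks higher than the untreated one, and without untreated replicate 2 it was 46 higher.

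The chloroplast and mitochondrial sequences together took a larger share of the peaks in each UV library than in either untreated one, which neither did alone. Organellar peaks were 27.9%, 22.4%, 13.6% and 28.1% of the list in UV replicates 1 to 4, and 8.31% and 11.4% in the untreated libraries. Group means were 23.0% ± 6.81 (SD, n = 4) with UV and 9.86% ± 2.19 (SD, n = 2) without, and 2 of the 15 splits gave a difference as large (exact permutation p = 0.133). Chloroplast peaks alone were 18.6% ± 6.32 with UV (n = 4) and 7.82% ± 4.85 without (n = 2, exact permutation p = 0.2), with UV replicate 3 at 10.2% and untreated replicate 2 at 11.2%. Mitochondrial peaks alone were 4.42% ± 0.948 with UV (n = 4) and 2.05% ± 2.66 without (n = 2, exact permutation p = 0.267), with UV replicates 1 and 3 at 3.91% and 3.34% and untreated replicate 1 at 3.93%. The 95% interval of UV replicate 3 for both organelles, 10.6 to 17.1%, overlapped that of untreated replicate 2, 8.96 to 14.3%. Chloroplast peaks numbered 135, 39, 46 and 155 in the UV libraries and 19 and 66 in the untreated ones, and mitochondrial peaks 22, 12, 15 and 35 against 17 and 1.

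**Figure D1:**
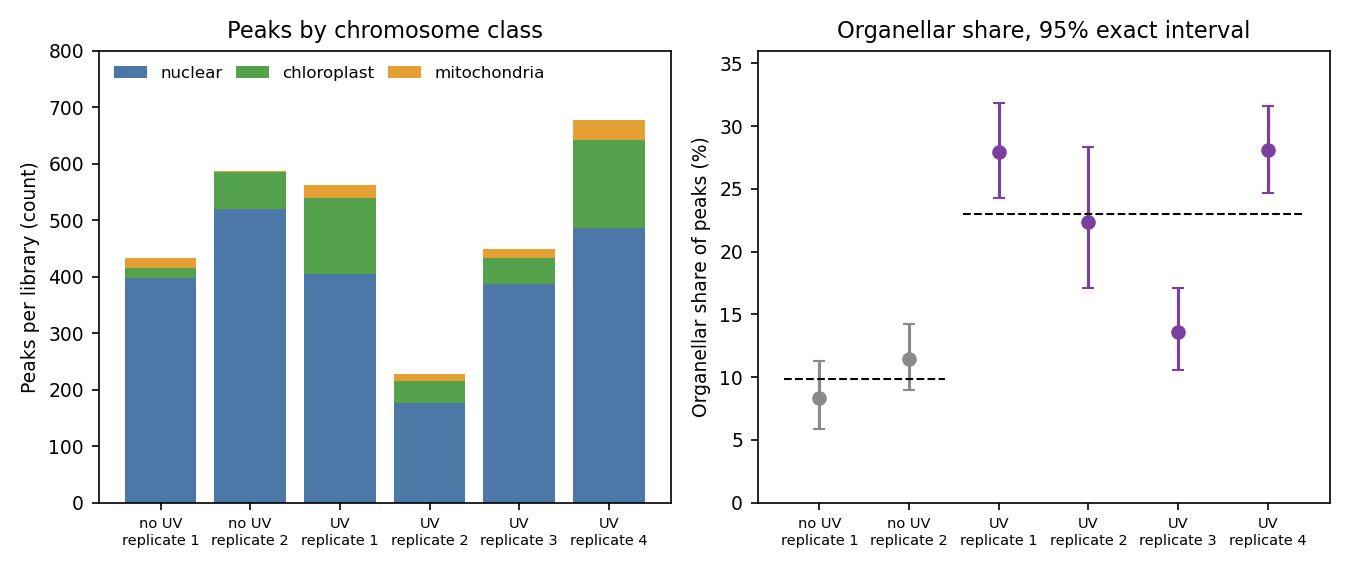
Left, number of peaks per library on nuclear, chloroplast and mitochondrial sequences, stacked; right, percent of each library's peaks on the organelles, with points for libraries, bars for exact 95% intervals and dashed lines for group means. The 4 UV libraries lie between 13.6% and 28.1%, and the 2 untreated libraries at 8.31% and 11.4%.

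Chloroplast peaks lay mostly before position 84224, as did most of the 101055 bp open to placement. After 110794 there were 18, 8, 4 and 25 peaks in UV replicates 1 to 4 and 1 and 16 in the untreated libraries. No library had a peak between positions 84224 and 110794 or after 127751, where the inverted repeats of the plastid genome lie. Peaks covered 46321 bp of the chloroplast in UV replicate 1 and 42322 bp in UV replicate 4. In the other 4 libraries they covered between 3237 and 12491 bp. The mean covered length was 26483 ± 20695 bp with UV (n = 4) and 7864 ± 6544 bp without (n = 2, exact permutation p = 0.267).

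**Figure D2:**
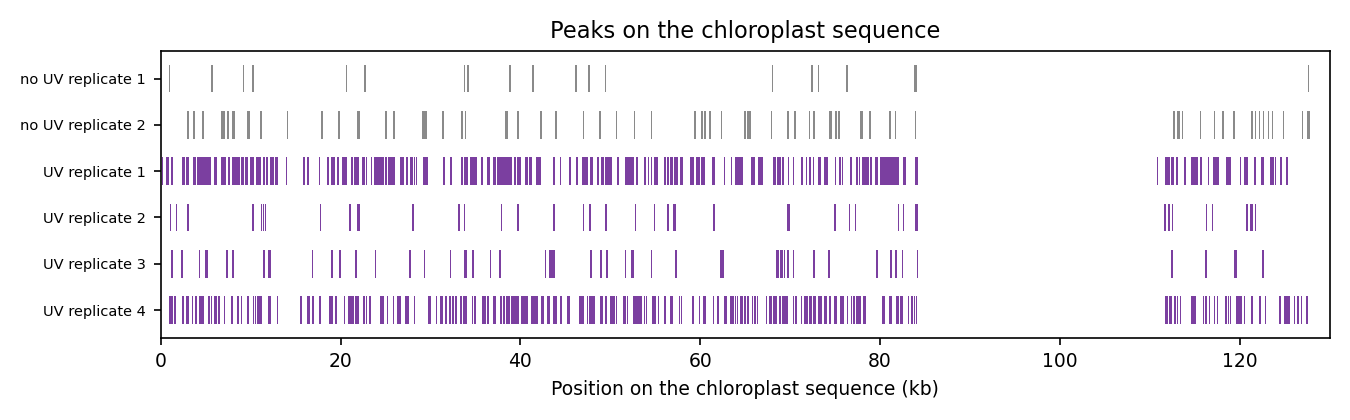
Peaks of each library along the chloroplast sequence in kb, untreated libraries in grey and UV libraries in purple; each bar is 1 peak drawn to scale. UV replicates 1 and 4 hold 135 and 155 peaks, and no library has a peak between 84224 and 110794.

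Nuclear peaks rarely recurred, but a small set recurred far beyond random placement, and most of that set was found with and without UV. Of 2249 nuclear regions, 2211 had a peak in 1 library. The remaining 38 compare with 5.73 per random placement (permutation p = 0.002, the smallest these placements can give), and 30 of the 38 had a peak in both groups. Each of the 15 pairs of libraries shared more nuclear peaks than placement gave, with median ratios of 53.1 for pairs of UV libraries, 38.97 for pairs of a UV with an untreated library and 26.7 for the untreated pair (permutation p = 0.002 in each pair, the smallest possible, and 0.00375 after adjustment). Placement gave least for pairs with UV replicate 2, the shortest list. Ratios of those pairs were 60.9 to 85.7 among UV libraries and 55.8 and 85.9 across groups. Without that list they were 39.1 to 45.2 among UV libraries and 30.3 to 41.0 across groups, so the order of the medians partly follows list length. Pairs of the same group had a mean Jaccard index of 5.90% and pairs across groups one of 3.49%. The excess lay in pairs of UV libraries, and on the chloroplast mostly in UV replicates 1 and 4, at 32.6%. Those 2 lists covered the most chloroplast sequence, 46321 and 42322 bp, and the index is not corrected for covered length. There, 107 peaks of UV replicate 1 overlapped UV replicate 4, against 80.1 by placement, a ratio of 1.336 (permutation p = 0.002). Median chloroplast ratios were 1.331 for pairs of UV libraries and 1.502 for pairs across groups. The untreated pair was less alike than the median pair across groups, at 1.96% against 2.64% on nuclear chromosomes and 2.35% against 8.51% on the chloroplast. On nuclear chromosomes alone the means were 3.49% and 2.67%. No other split of the libraries gave a difference as large over all chromosomes or on the nuclear ones, so the one-sided exact p of 0.0667 in both is the smallest possible. On the chloroplast alone it was 0.133, and over all chromosomes it was 0.2 with lists of equal length and 0.2 among peaks above the median score. The difference over all chromosomes was 0.805 percentage points without UV replicate 1 and 0.982 without UV replicate 4, against 2.41 with all libraries.

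All 6 libraries had a peak in 14 regions, 9 nuclear and 5 on the chloroplast. Random placement gave a mean of 1.27 and no nuclear one (permutation p = 0.002, the smallest possible). The highest ranked lay in AT5G61520 on chromosome 5 at 24741295 to 24741594, followed by AT3G23460 on chromosome 3 at 8413948 to 8414251. On chromosome 2, the region at 11839450 to 11839749 lay 2487 bp from AT2G27775, and that at 9723111 to 9723455 lay 160 bp from SQE2, a squalene epoxidase gene. A further one at 9798 to 10236 on chromosome 2 overlapped the non-coding RNA gene AT2G00340. The chloroplast region at 67602 to 70005 overlapped rpl33, rps18, rpl20, rps12 and clpP. On chromosome 5, a pericentromeric region at 12593363 to 12593665 lay 459 bp from AT5G33330, and one at 23730743 to 23734216 overlapped DDB2. The mean score percentile in UV lists was between 95.2 and 99.6 for these 8. Some of the 14 regions were chains in which not all libraries overlapped each other. In the DDB2 region, no peak of untreated replicate 1 overlapped one of untreated replicate 2.

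UV-only recurrent regions were mostly organellar. There were 65, of which 46 lay on the chloroplast, 12 on the mitochondrial sequence and 7 on nuclear chromosomes. Random placement gave 41.9 on average (permutation p = 0.002, the smallest possible), with 32.8 on the chloroplast (permutation p = 0.004), 7.02 on the mitochondrial sequence (permutation p = 0.0579) and 2.06 on nuclear chromosomes (permutation p = 0.0140). Regions with a peak both with and without UV exceeded placement too, so this excess is not particular to UV. They numbered 94 against 55.2, and 60 against 47.6 on the chloroplast (permutation p = 0.002 in both). Over all chromosomes 4 of the 15 splits gave at least 65 regions of the UV-only kind (one-sided exact p = 0.267), up to 82 when untreated replicate 1 and UV replicate 2 were set against the rest. This count of 65 became 104 without untreated replicate 2, 28 without UV replicate 1 and 36 without UV replicate 4. On nuclear chromosomes, 6 of the 15 splits gave at least as many as the 7, up to 11 (one-sided exact p = 0.4). On the mitochondrial sequence alone the 12 were the highest of all splits, with 11 in the next (one-sided exact p = 0.0667, the smallest possible). This did not hold for regions in at least 3 of the 4 libraries, with 3 in 2 of the 15 splits (one-sided exact p = 0.133), or in all 4, with 0. Untreated replicate 2 had 1 mitochondrial peak, so it could remove hardly any mitochondrial region.

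Of the UV-only recurrent regions, 6 had a peak in all 4 UV libraries. At least 6 were given by 3 of the 15 splits, up to 7 (one-sided exact p = 0.2), so this count did not set UV apart. The chloroplast ones among the 6 regions were chains of peaks, and no base of theirs was covered by all 4 libraries. A pericentromeric one on chromosome 4 at 4547945 to 4548093 lay 117 bp from the pseudogene AT4G07747, and one on chromosome 5 at 14739445 to 14739742 lay in the protein-coding gene AT5G37240. The other 4 were on the chloroplast: 56604 to 57528 in accD, for a subunit of acetyl-CoA carboxylase, 82236 to 82838 in the ribosomal protein genes rpl16 and rps3, 27635 to 28310 over petN, for a cytochrome b6f subunit, and 11608 to 12550 in atpF, for an ATP synthase subunit. Among regions in 3 UV libraries, the chloroplast ones ranked highest overlapped psbC (34366 to 35231), rpoC2 (18668 to 19167), trnK with matK (2311 to 2762), cemA (61291 to 61635) and ndhD (116142 to 116392). The nuclear ones lay in AT4G32700 on chromosome 4 at 15769698 to 15769973 and in AT2G45620, also named URT1, an RNA uridylyltransferase gene, on chromosome 2 at 18792981 to 18795763. The remaining 2 were mitochondrial, at 362082 to 362507 and 350985 to 351388.

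In the opposite direction, 2 regions had a peak in both untreated libraries and in no UV library, against 0.944 by placement (permutation p = 0.494). One lay in RALFL34, a gene for a small signalling peptide, on chromosome 5 at 26768304 to 26768494, and the other on the mitochondrial sequence at 202380 to 202607. The median over the 15 splits was also 2.

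Over whole lists, nuclear peaks lay in protein-coding genes slightly more often than random placement gave, with or without UV. They lay less often than that in genes classed as pseudogenes, which may include transposable element genes. Placement did not leave out assembly gaps or repeats to which reads cannot be assigned. This raises what it gives for pseudogenes and pericentromeres, and lowers it for protein-coding genes, to an extent not measured. The protein-coding share was 60.9% ± 3.82 with UV (n = 4) and 60.3% ± 0.129 without (n = 2, exact permutation p = 0.867). It was above the placement mean in all 6 libraries and past the adjusted threshold in 5, with UV replicate 2 at 55.4% against 53.9% (adjusted permutation p = 0.719). Pseudogenes held 4.76% ± 0.599 with UV (SD, n = 4) and 3.30% ± 0.318 without (SD, n = 2), each UV library being above each untreated one (exact permutation p = 0.0667, the smallest possible). The shares were 4.94%, 5.08%, 3.87% and 5.13% in UV replicates 1 to 4 and 3.53% and 3.08% in the untreated libraries. Placement gave 8.66 to 9.03%, and the pseudogene share was below it in all 6 libraries and past the adjusted threshold in 5, UV replicate 2 having an adjusted permutation p of 0.108.

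Pericentromeres held 12.02% ± 0.334 of nuclear peaks with UV (SD, n = 4) and 10.5% ± 0.176 without (SD, n = 2). Each UV library was above each untreated one, which gives the smallest exact permutation p possible, 0.0667. Random placement gave 14.5 to 14.97%, and the share was below it past the adjusted threshold in both untreated libraries (adjusted permutation p = 0.0229 and 0.0180) and in no UV library. Every interval was wider than this gap, for example 8.87 to 15.4% in UV replicate 1 and 7.51 to 13.7% in untreated replicate 1. Among peaks above the median score of their list the order turned, with 18.6% ± 3.79 with UV (n = 4) and 29.0% ± 5.34 without (n = 2, exact permutation p = 0.0667). The protein-coding share of those peaks was 47.3% ± 2.21 with UV (n = 4) and 37.3% ± 4.07 without (n = 2, exact permutation p = 0.0667). In both groups the protein-coding mean was then below the 53.9 to 54.3% that placement gave for whole lists. The pericentromeric mean was above the whole-list placement range in both. The higher-scoring peaks were not placed on their own. That filter kept 16.6% and 24.2% of the untreated lists and 23.8% to 50% of the UV lists, because of tied scores. With the highest 16.6% of every list, an alternative chosen after seeing the data, the pericentromeric shares were 27.1% ± 3.64 with UV (n = 4) and 31.01% ± 2.51 without (n = 2, exact permutation p = 0.4). The protein-coding shares were then 45.6% ± 7.21 and 40.3% ± 8.29 (exact permutation p = 0.533, n = 4 and 2).

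Of the 29 genes fixed by identifier, 3 carried a peak in any library. DDB2, whose protein recognises UV lesions in nucleotide excision repair, had peaks in all 6: 1, 2, 4 and 3 in UV replicates 1 to 4 and 2 and 4 in the untreated ones. The UV replicate 1 peak, at 23730836 to 23734216 on chromosome 5, was 3381 bp wide, covered 88.2% of the gene and had the highest score of that list, 39.4. In the other libraries peaks covered between 7.92% and 28.6% of the gene, the latter in untreated replicate 2. UVR3, a photolyase gene, had 1 peak, in UV replicate 1 at 5295109 to 5295255 on chromosome 3, and RDR6, an RNA-dependent RNA polymerase gene of RNA silencing, had 1, in UV replicate 3 at 18350770 to 18350914 on chromosome 3. Both peaks had the narrowest width of their list. Placement gave 0.021 photolyase genes in UV replicate 1 (adjusted permutation p = 0.206) and 0.235 RNA silencing genes in UV replicate 3. Neither list passed the adjusted threshold.

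None of the other 12 repair genes, PHR1, the 4 genes of UV-B and light response (UVR8, HY5, COP1 and CHS) or the other 9 RNA silencing genes had a peak. Placement gave at most 0.285 genes of any identifier list per library, so this absence says little. UV-only recurrent regions overlapped 5 of 662 tRNA genes, against 6.17 by placement. They overlapped 0 members of each identifier list and of the rRNA, snoRNA with snRNA, miRNA and pseudogene lists. Placement gave means of at most 0.006 for the identifier lists and 0.903 for pseudogenes. For rRNA, snoRNA with snRNA and miRNA genes it gave at most 0.02. With so few expected, 0 could show no shortage and says nothing about these genes. No list passed the permutation test adjusted over the 9 lists, nor at an unadjusted p of 0.05. A further test took regions in at least 2 UV libraries whatever the untreated ones showed. There 1 of 11 rRNA genes was overlapped, AT3G41768, against 0.001 by placement (adjusted permutation p = 0.0360). The result rests on this 1 gene, whose region had a peak in 3 UV libraries and in 1 untreated one. Per library, pseudogenes were overlapped less often than by placement in every library. Both untreated libraries and UV replicate 4 passed the adjusted threshold, with 15, 19 and 26 genes against 37.0, 47.8 and 44.6 (adjusted permutation p = 0.0360 in each). UV replicate 3 had 17 against 36.5 (adjusted permutation p = 0.0539).

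**Figure D3:**
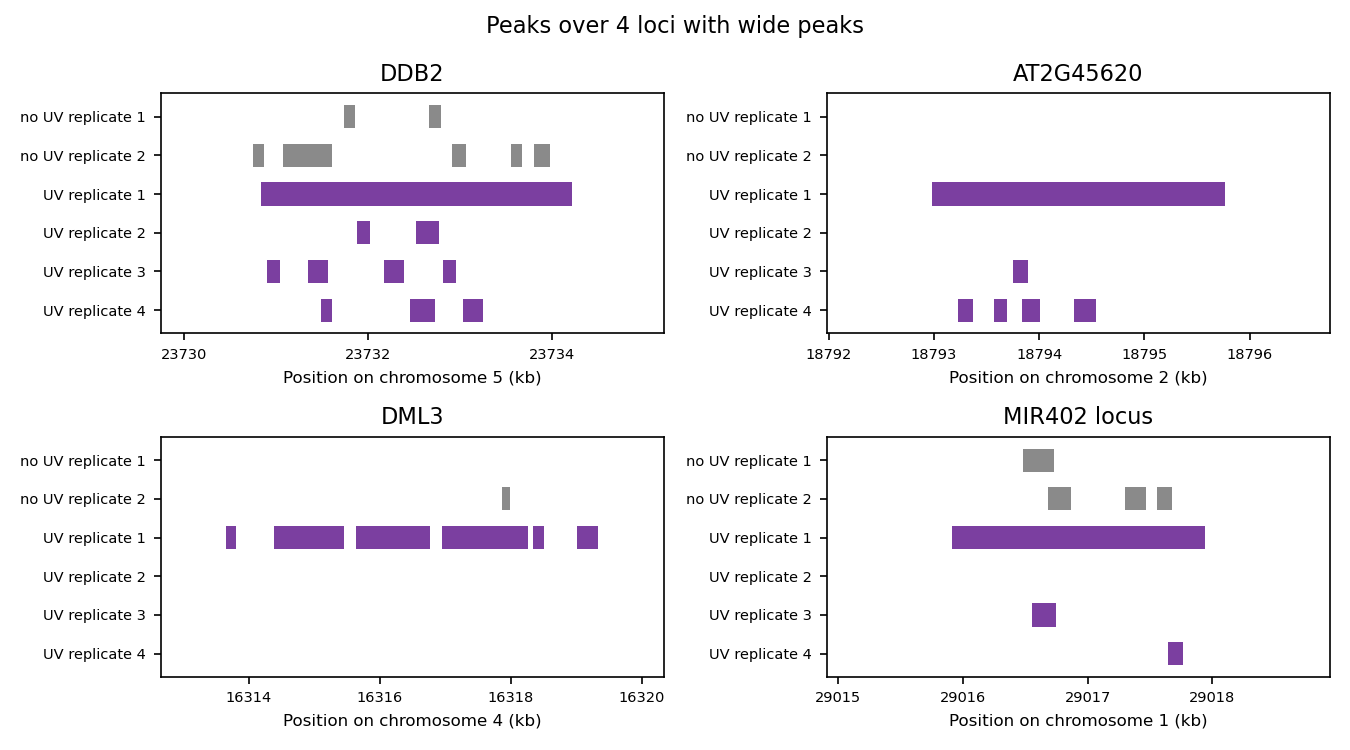
Peaks of each library over 4 nuclear loci in kb on TAIR10, untreated libraries in grey and UV libraries in purple; each bar is 1 peak drawn to scale. UV replicate 1 has a peak of 3381 bp over DDB2, where the 2 untreated libraries also have peaks, and one of 2783 bp over AT2G45620.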

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

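All tests of explanations in this part were chosen after the results they bear on had been seen, at least in part.

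Among 15 per-library measures, 2 had a UV library far from the other 3. UV replicate 4 had the highest pericentromeric share of nuclear peaks, 12.5%, with the others between 11.85% and 11.86%. UV replicate 3 had the lowest pseudogene share, 3.87%. Chance gives such a distance in about 1 in 20 groups.

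The organellar share of peaks was higher in each UV library than in either untreated one, which neither organelle alone showed. Deeper UV libraries that raise peak numbers alike on all chromosomes would leave the share unchanged, so by definition they cannot raise it. With UV, nuclear peaks were 0.794 times as many and organellar peaks 2.23 times. The organellar factor is uncertain (114.75 ± 69.3 organellar peaks, n = 4, against 51.5 ± 21.9, n = 2, exact permutation p = 0.267). It would need 1022 nuclear peaks, or 798 to 1265 with a library left out, and UV libraries had 177 to 487. These numbers restate the higher share and are no separate test of depth. Depth acting unequally on nuclear and organellar sequence was not tested and stays open. UV lesions at fixed chloroplast positions stay open. UV-only recurrent chloroplast regions numbered 46 against 32.8 by placement (permutation p = 0.004), while 4 of the 15 splits gave as many, up to 64. The mean Jaccard index there was 11.8% within and 7.09% between groups (one-sided exact p = 0.133), uncorrected for the length covered. Chloroplast peaks shared relative to placement showed no such excess. Median ratios were 1.331 for pairs of UV libraries (1.16 to 1.82) and 1.502 for pairs across groups (1.29 to 2.43). More chloroplast DNA or reads in the UV libraries also cannot be told apart from lesions, because read numbers per sequence are unknown and the exact permutation p of the share is 0.133.

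Nuclear regions with a peak both with and without UV numbered 30, against 3.22 by random placement (permutation p = 0.002, the smallest possible), so lesions made by the treatment cannot be their whole cause. Repeated sequence collapsed in the reference may contribute, since 46.7% of them were pericentromeric, against 9.45% of regions found in 1 library (one-sided Fisher exact p = 2.15e-07). With regions less than 10 kb apart joined, the shares were 36% and 9.41% (exact p = 0.000342). Lesions or antibody binding in heterochromatin without UV would give the same share and were not tested. The regions compared also differed in score. Nuclear peaks of regions in 1 library had a median score percentile of 53.7, those of regions in 2 or more libraries one of 89.9. Among the highest 16.6% of each list by score, 21.8% to 32.8% of nuclear peaks were pericentromeric. The contrast may therefore follow peak score rather than recurrence.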

How the results depend on the processing

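Of 106 alternatives, 83 kept the direction of a group difference or a count within 1.5 times, 9 turned a direction and 14 moved a count further. No group difference could pass 0.05 under any of them, so kept directions say nothing about significance. Alternatives on peaks wider than the narrowest width, on organelles alone, on each organelle, on chloroplast genes and on the same fraction of each list were chosen after seeing the data. The organellar share difference stayed positive throughout, at 11.4 to 16.3 percentage points with a library left out.

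The difference in peak number, -31 in the full comparison, ran from -108 to 52.7 with 1 library left out and was 60.25 among peaks wider than the narrowest width. Covered length turned from 17417 to -3624 bp on nuclear chromosomes alone, so its excess lay on the organelles. The pericentromeric difference turned from 1.57 to -10.4 percentage points among peaks above the median score, which kept unlike fractions of the lists, 16.6% to 50%, because of tied scores. With the highest 16.6% of each list by score it was -3.87 (exact permutation p = 0.4). The protein-coding difference, 0.583, ran from -0.344 to 2.42 with a library left out. The cause was not tested.

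UV-only recurrent regions numbered 28 to 104 with a library left out, against 65. They were 7 on nuclear chromosomes, 22 when at least 3 UV libraries were asked for and 6 when all 4 were. Regions in both untreated libraries only, 2 in all, were 2 to 4 without a UV library, 1 among peaks above the median score, 1 on nuclear chromosomes and 0 with an overlap of 0.5 of the shorter peak. Leaving out an untreated library gives this count no value. Regions in all 6 libraries, 14, were 7 above the median score, 9 on nuclear chromosomes and 9 among wider peaks. Gene lists passing the test went from 0 to 1 with regions in at least 2 UV libraries whatever the untreated ones showed. Placement within pericentromere or arm gave 41.8 UV-only regions, against 41.9.

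The groups share replicate numbers 1 and 2, and whether equal numbers pair the libraries is not known. Over all chromosomes the Jaccard index of same-numbered libraries was 2.90% and 3.56%, that of differently numbered ones 5.24% and 3.72%. On nuclear chromosomes it was 2.85% and 2.70%, against 3.06% and 3.32%. So few values cannot decide. With a replicate block on those 4 libraries the peak number difference was -115 and the protein-coding difference turned to -1.99 percentage points. The block turned no other direction. Alternatives for transposable element genes, dipyrimidine steps, GC content and repeated sequence were not run, since those results were not analysed here. Gene bodies were extended by 1000 bp on both sides, as strand was not used.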

Other observations

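The tests in this part were chosen after the peaks had been seen. A stretch of chromosome 3 that holds the rRNA gene AT3G41768 carried 8 regions between 14194218 and 14202479. The region at 14202154 to 14202479, in AT3G06365, had a peak in 4 UV libraries and 1 untreated one, and that at 14198814 to 14199111, in AT3G41768, in 3 and 1. The other 6 regions found in all 6 libraries overlapped psaB with psaA, psbD with psbC, trnL, and rpl22 with rps19 on the chloroplast, or lay 7577 bp from AT3G33055 and 2832 bp from AT4G06700 in pericentromeres. The other 3 nuclear UV-only recurrent regions, each in 2 UV libraries, overlapped AT5G37430 with AT5G37440, AT3G27510 and AT4G30090. UV-only recurrent regions took 21.9% of the chloroplast sequence open to placement and overlapped 42 of 95 chloroplast genes there, against 37.1 by placement (permutation p = 0.240). No group of chloroplast genes stood apart: they overlapped 8 of 20 photosystem genes against 7.19 by placement, 4 of 6 cytochrome b6f genes against 2.28 and 2 of 4 RNA polymerase genes against 3.00 (adjusted permutation p = 1 in each).

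Peaks wider than 600 bp on nuclear chromosomes numbered 7, at 5 loci, and 6 of them were in UV replicate 1. They lay over DDB2, AT2G45620 (URT1), the DNA demethylase gene DML3, the locus of AT1G77230 with MIR402, and RPL24A, the last in UV replicate 4 at 15350464 to 15351385 on chromosome 2. In UV replicate 1, 6 peaks covered 68.6% of DML3, and 1 peak of 2783 bp covered 91.5% of AT2G45620. A peak of 2032 bp covered all of MIR402, a microRNA for which DML3 is a known target. Untreated libraries had peaks there too: they covered 67.0% and 46.9% of MIR402 in untreated replicates 1 and 2, and 2.01% of DML3 in untreated replicate 2. AT2G45620 and RPL24A had none without UV. Within 20 kb of DDB2, AT2G45620, DML3 and AT1G77230, over all 6 libraries, there were 1, 1, 0 and 1 further peaks.

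Lesions made by the UV treatment are argued against as the whole cause at DDB2, since the 2 untreated libraries had 6 peaks on the gene, more than placement in each (one-sided permutation p = 0.001, the smallest possible). At AT2G45620, with peaks in 3 UV and 0 untreated libraries, they stay open, since the locus was picked for its wide UV peak and 6 libraries are too few to decide. A hypothesis left open is that cloned or amplified gene DNA was carried over into some libraries: on average 94.9% of the wide peaks of a locus lay inside 1 gene, but the loci were picked for this outline, so the value is no support. Coverage of exons alone or vector junctions in reads would decide, and reads were not analysed here. A process that follows the transcribed unit would give the same outline and was not tested.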
